A study of Mus musculus with 23 samples.

How the data were processed

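RNA from spleens of 10-week-old males of the mouse strains DBA/2J and C57BL/6J was measured on 23 one-colour Illumina expression arrays. Per the labels, each array held a pool made from the spleen RNA of 2 mice, mixed in equal parts. The groups were unirradiated control, low dose (10 cGy of gamma rays at 9 cGy per hour from a 137Cs source) and high dose (1 Gy at 6 Gy per minute from a 60Co source), all taken 24 h after exposure. Each group had 4 pools, except DBA/2J low dose with 3. The source names of irradiated samples also carry the word control, so the dose was read from the treatment label. Dose, dose rate and radiation source change together in this design and cannot be told apart. P-values measure the spread between pools of 2 mice, not between single mice.

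The deposited table of signals holds 1 intensity per probe and array on a linear scale, not normalized, as the authors exported it per the file headers. Beside each signal the authors deposited a detection p-value, the position of the probe against the background of its array. The authors' processed values are on a log2 scale and nearly share their quantiles between arrays, as seen from the values. Per the submitters' processing notes lumi was used, and its version is not given in the sources used here. The scanner software is also not given in the sources used here. The array medians of the authors' values lay between 8.09 and 8.10. Each array's signals had a Spearman correlation of 1 with its own column of authors' values, and 23 of 23 arrays matched their own column best after each probe was centred. The exact transform and centring of the authors' values stay unknown, so they served only as an alternative.

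The signals were processed with limma 3.58.1 in R 4.3.3. The table has no negative control probes, so the background mean and SD of each array were inferred from the detection p-values, followed by normexp correction with an offset of 16, quantile normalization and log2. This inference set the background mean of each array (158 to 227) above the array's signal at a detection p of 0.05 (104 to 140). Undetected probes and also dim detected probes therefore lay below it. The normalized floor therefore lay near 7.79, the median of all values was 7.88, and changes of dim genes are compressed towards 0. Probes were kept if the detection p was under 0.05 on at least 3 of the 23 arrays, which left 18423 of 34492 probes. Gene names came from the platform annotation, in which 20256 probes have 1 gene symbol, 9 have several and 14227 have none. Of these, 20213 were matched to the mouse gene table by gene number, which changed 0 symbols. Each symbol was represented by its brightest probe, and probes without a symbol were tested one by one, giving 17176 features, 11348 of them with a symbol. Probes bind fixed sequences, so DBA/2J variants under a probe can lower or raise its signal without a change in the transcript.

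A model with 6 group means was fitted to all 23 arrays with lmFit and eBayes. It gave 9 comparisons: each dose against control in each strain, the 2 control groups, high against low dose in each strain, and the strain difference of each dose effect (an interaction). P-values were adjusted by Benjamini-Hochberg over all features of a comparison and called at 0.05. Changes are log2 fold changes with their standard error. Where a probe was detected on none of a group's arrays, the fold is a bound, written "at least". It sets the mean of the brighter group against the mean, over the dimmer group's arrays, of the higher of the lowest detected signal and the probe's own signal.

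In total 23 gene lists with 625 members, 457 of them measured, were fixed before the data were examined, as were the model, the rule for named genes and the alternatives not called added. They cover erythroid, neutrophil and granulocyte, megakaryocyte and platelet, B cell, germinal centre and plasma cell, T cell, NK cell and cytotoxic, macrophage and monocyte, dendritic cell, and stromal and endothelial markers, and carry-over of pancreas and adipose tissue. The others are p53 target genes, DNA double-strand break repair, DNA replication, mitosis and G2/M, interferon-stimulated genes, inflammatory and NF-kB response genes, NRF2 antioxidant genes, oxidative phosphorylation, MHC class II antigen presentation, immediate-early and heat shock genes, ribosomal proteins, and genes at known differences between the strains. Lists were tested with camera at a preset correlation of 0.01 between genes and, beside it, with the estimated correlation. Members were also counted with p-values adjusted over the list alone. The mean of each list per pool was compared by a two-sided exact permutation test.

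Named genes are, per comparison, the 12 largest rises and the 12 largest falls among called genes whose groups did not overlap (no such condition for interactions), up to 4 called members per list, and 6 p53 targets whatever their values. Of these 6, Bax and Eda2r were not analysed here. Clone names were passed over.

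The steps were tested on simulated data in which 200 of 17176 genes were changed. For high dose against control in C57BL/6J, 95% of genes changed by 1 log2 unit and 78% of those changed by 0.5 were recovered, and 4.95% of the calls were false. For low dose against control in DBA/2J the shares were 92%, 81% and 7.49%. The simulated genes varied independently, each with 1 spread for all groups. Real genes vary together, and the first component of the residuals held 31.2% of their variance. The DBA/2J low dose pools also varied more, with a B cell list SD of 0.75 against 0.067 in C57BL/6J high dose pools. The shares of false calls therefore do not carry over to the real calls. The number of arrays limits the precision of every value.

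Alternatives covered the background correction, the normalization, the filter, the authors' values, the several probes of a gene, the variance model, array weights, the arrays in the model, each pool left out in turn, and the estimated correlation. Alternatives added after seeing the data were normexp with an offset of 50, the order of the pool numbers as a block, and erythroid and granulocyte scores as covariates. Also added were fits without the pools with pancreatic transcripts and fits without DBA/2J low dose pools 1 and 3. The files show no slide or scan, so no slide could be used as a block. The sample names carry pool numbers, and each group was split into its 2 lowest numbers (12 arrays in total) and the rest (11 arrays). The sign of the second component of the residuals, with 19.1% of their variance, followed this split on 22 of 23 arrays. The order of the pool numbers was therefore treated as a possible batch, and values within each part are given. The ranges of the pool numbers overlapped in 0 of 15 pairs of groups, so the block and the parts bear only on a batch within groups, and a batch between groups cannot be told apart from strain and dose.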

Results

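The data are spleen expression profiles of C57BL/6J and DBA/2J mice, the parent strains of the BXD recombinant inbred lines, 24 h after 10 cGy (low dose), 1 Gy (high dose) or no irradiation. There were 4 pools of 2 mice in each group, and 3 in the DBA/2J low dose group. Between 14233 and 16002 probes per array were detected, and the median signal ranged from 99.8 to 137. No 2 arrays of a group shared more than 1 exactly equal probe signal of 34492. Values below are log2 fold changes ± SE from limma with Benjamini-Hochberg adjustment unless another measure is named.

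**Figure D1:**
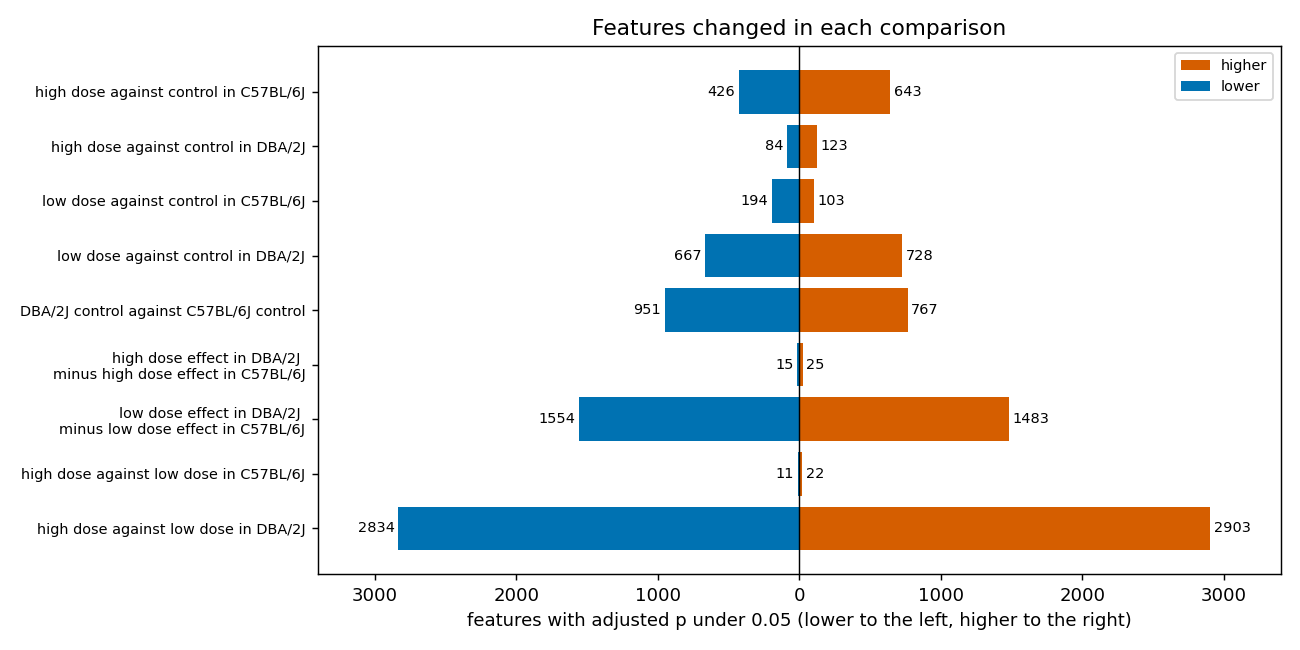
Number of features with an adjusted p under 0.05 in each comparison, with lower features drawn to the left and higher features to the right of 0. High against low dose in DBA/2J had 2903 higher and 2834 lower features, and high against low dose in C57BL/6J had 22 and 11.

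The first comparison asked what the high dose changed in C57BL/6J spleens, and the lowest values were those of red cell precursor transcripts. Slc4a1, the anion exchanger of the red cell membrane, changed by -5.27 ± 0.42, Alas2, the first enzyme of erythroid heme synthesis, by -4.69 ± 0.38, and Klf1, an erythroid transcription factor, by -4.42 ± 0.52. Of 27 measured erythroid markers, 21 fell (26 adjusted over the list alone), with a median of -3.08 and an adjusted p = 2.00e-42, or adjusted p = 0.0263 with an estimated correlation. Granulocyte transcripts fell as well, among them Ltf (lactoferrin, -4.25 ± 0.64), Mpo (myeloperoxidase, -4.21 ± 0.57) and the granule protein genes Ngp (-4.07 ± 0.65) and Camp (-4.00 ± 0.57). In that list 12 of 17 members fell (15 adjusted over the list alone, median -1.85, adjusted p = 3.44e-21, and adjusted p = 0.0308 with an estimated correlation). Of 14 megakaryocyte and platelet markers 4 fell (12 adjusted over the list alone, median -0.63), with Treml1 at -1.83 ± 0.33 and Gp5 at -1.68 ± 0.31. That call (adjusted p = 4.66e-12) became adjusted p = 0.112 with an estimated correlation.

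Genes of cell division were lower too. Of 29 DNA replication genes 11 fell (19 adjusted over the list alone, median -0.75), with the helicase subunit Mcm2 at -1.91 ± 0.44 and the ribonucleotide reductase subunit Rrm1 at -1.85 ± 0.37. The list had an adjusted p = 1.23e-17, and adjusted p = 0.171 with an estimated correlation. Of 27 mitosis and G2/M genes 12 fell (14 adjusted over the list alone, median -1.08, adjusted p = 1.57e-16, and adjusted p = 0.134 with an estimated correlation). Birc5 (survivin) changed by -2.76 ± 0.40 and the spindle midzone gene Prc1 by -2.55 ± 0.38. The Mcm2 call was lost without C57BL/6J control replicate 2 or 4, with an adjusted p of up to 0.0535.

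Targets of p53 rose, although most members moved little. Cdkn1a, the cell cycle inhibitor p21, rose by 1.60 ± 0.18 and Ccng1 (cyclin G1) by 1.34 ± 0.11, followed by Dcxr at 0.76 ± 0.13 and Phlda3, a repressor of Akt, at 0.70 ± 0.08. Mdm2, the ligase that degrades p53, was measured at 0.62 ± 0.19 and missed the threshold (adjusted p = 0.0577). Of 30 p53 targets 8 rose (16 adjusted over the list alone, median 0.11, adjusted p = 1.67e-06, and adjusted p = 0.0263 with an estimated correlation). With the erythroid and granulocyte scores as covariates, added after seeing the data, the values of Cdkn1a, Ccng1 and Phlda3 were 1.84 ± 0.41, 1.11 ± 0.24 and 0.89 ± 0.19. Their larger standard errors gave an adjusted p = 0.172 each. Mdm2 was at -0.36 ± 0.33 with these covariates, and the p53 list was still called (median 0.10, adjusted p = 0.000181).

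Lymphoid and stromal transcripts were higher in high dose C57BL/6J pools. Of 15 NK cell and cytotoxic markers 6 rose (11 adjusted over the list alone, adjusted p = 8.28e-09, and adjusted p = 0.0279 with an estimated correlation), among them the NK receptor genes Klre1 (0.72 ± 0.13) and Klrd1 (0.69 ± 0.13). Of 22 T cell markers 5 rose (10 adjusted over the list alone), with the T cell costimulator Cd28 at 0.35 ± 0.07, and the list had an adjusted p = 7.77e-06, or adjusted p = 0.203 with an estimated correlation. Of 18 stromal and endothelial markers 3 rose (9 adjusted over the list alone), among them the B cell chemokine Cxcl13 (0.87 ± 0.19), with an adjusted p = 6.79e-05, or adjusted p = 0.171 with an estimated correlation. The proteasome subunit Psmb1 rose most of all named genes (2.76 ± 0.30), and Lyz1 (lysozyme) rose by 1.25 ± 0.11 and the matrix protease Mmp2 by 1.19 ± 0.18. With the erythroid and granulocyte scores as covariates, which take up most of the dose effect by construction, 13 of the 17 called lists of this comparison turned direction, among them T cell (median -0.23), stromal (-0.080), B cell (-0.99), DNA replication (0.75) and mitosis (0.26) genes, and 2 kept call and direction.

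Among the other lists of this comparison, B cell (median 0.38, adjusted p = 0.000868), macrophage and monocyte (0.43, 0.000341), MHC class II (0.36, 0.00441), inflammatory and NF-kB (0.15, 0.0117), dendritic cell (0.13, 0.0350) and strain-difference genes (0.10, 0.0420) were shifted up, and double-strand break repair (-0.07, 0.000868) and oxidative phosphorylation (-0.02, 0.0277) down. None of these 8 was called with an estimated correlation, where the adjusted p values lay between 0.187 and 0.394. The dendritic cell call was lost without control replicate 4 or high dose replicate 2 or 4 (adjusted p up to 0.0957). That of the strain-difference genes was lost without control replicate 2 or 3 or high dose replicate 1, and that of oxidative phosphorylation without high dose replicate 1 (adjusted p up to 0.0946 for both). Interferon-stimulated genes (median 0.16, mean -0.05) had 6 members higher, such as Parp14 (1.02 ± 0.17), and 2 lower, the antiviral gene Rsad2 (-3.54 ± 0.36) and Isg20 (-1.55 ± 0.27), with an adjusted p = 0.111. NRF2 antioxidant genes (adjusted p = 0.252, with Gclm at -2.64 ± 0.36), immediate-early and heat shock genes (0.429), pancreas and adipose carry-over markers (0.400, median 0.13, mean 0.09, test direction down), germinal centre and plasma cell markers (0.689) and ribosomal proteins (0.689) were not called.

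In total 1069 features changed at high dose in C57BL/6J, 643 of them higher (against 3417 at an unadjusted p under 0.05). The groups did not overlap for 2913 features, which is 17% against 2.86% by chance. Median scaling in place of quantile normalization gave 65 higher and 281 lower. The count fell to 642 and 639 without control replicate 2 or 4, and to 655 and 684 without high dose replicate 1 or 2. Pancreatic transcripts stood out in control replicate 1 and high dose replicate 1, and without both pools 652 features were called. Within the lower and within the higher pool numbers the erythroid median was -2.93 and -3.23, the granulocyte median -1.83 and -1.88, and 9 and 762 features were called, and 1460 with the pool-number order as a block.

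**Figure D2:**
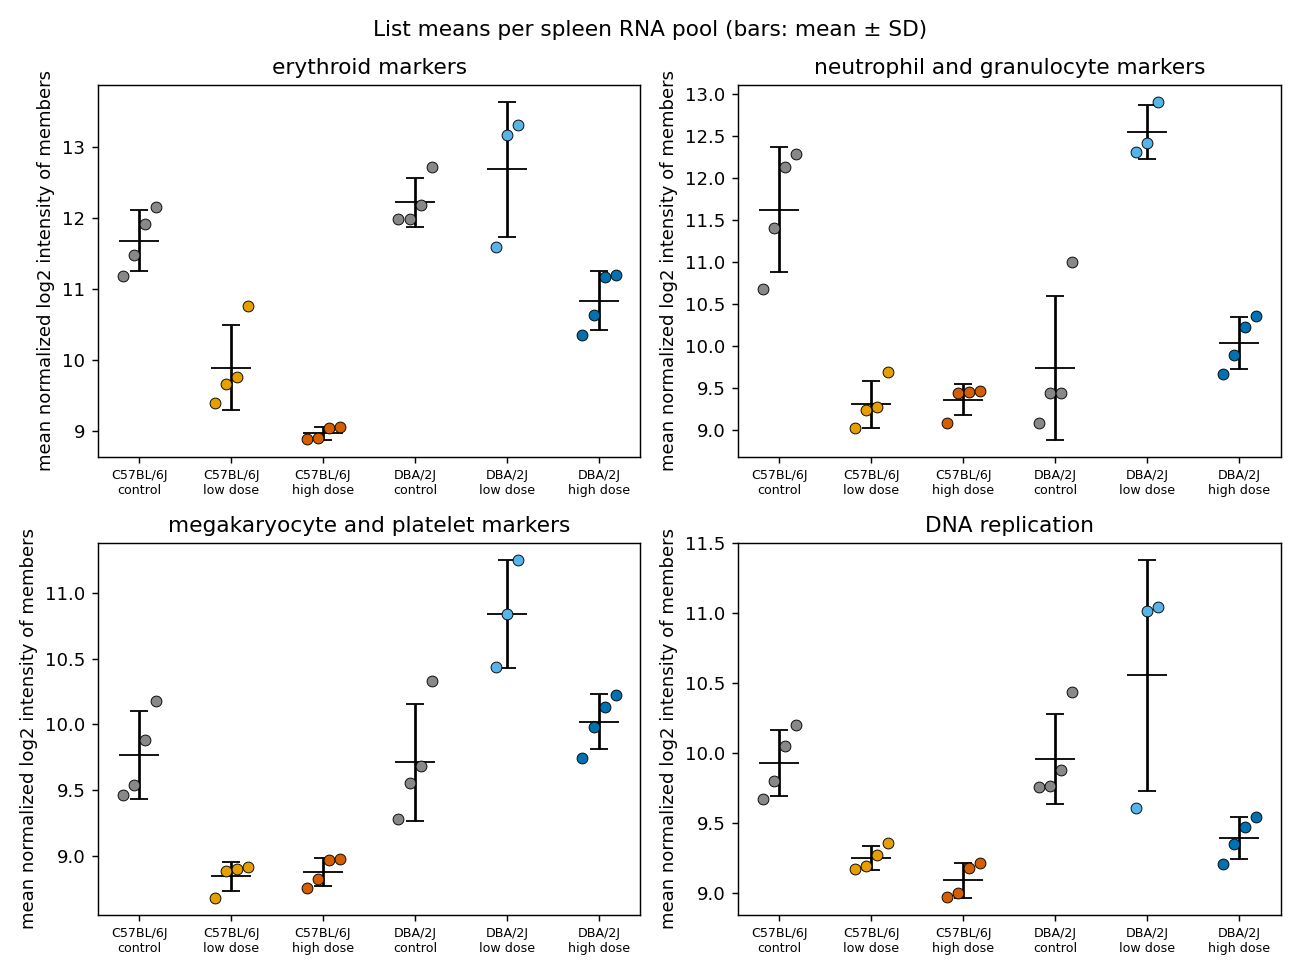
Mean normalized log2 intensity of the members of 4 gene lists in each spleen RNA pool (points), by strain and dose, with horizontal lines for the group mean and bars for ± SD. The erythroid mean of the 4 high dose C57BL/6J pools lay between 8.88 and 9.05 and that of their controls between 11.19 and 12.15.

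High dose against control in DBA/2J addressed the same dose in the other strain. Red cell transcripts fell, among them the globin gene Hbq1b (-2.84 ± 0.41), Hemgn (hemogen, -2.27 ± 0.53), Sptb (the red cell spectrin beta chain, -2.15 ± 0.45) and Ermap (-2.14 ± 0.49). Of 27 erythroid markers 8 fell (22 adjusted over the list alone, median -1.43, adjusted p = 1.44e-26, and adjusted p = 0.134 with an estimated correlation). Of 27 mitosis and G2/M genes 4 fell (12 adjusted over the list alone, median -0.60), with Nusap1 at least 3.57-fold lower and Birc5 at -1.76 ± 0.40. That list had an adjusted p = 2.33e-15, and adjusted p = 0.306 with an estimated correlation. DNA replication genes had a median of -0.50 with an adjusted p = 7.70e-14, or adjusted p = 0.354 with an estimated correlation, and limma called 0 of 29 members (0 adjusted over the list alone, 13 lower at an unadjusted p under 0.05).

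Of 30 p53 targets 4 rose in DBA/2J at high dose (9 adjusted over the list alone, median 0.07, adjusted p = 8.77e-07, and adjusted p = 0.0342 with an estimated correlation). Ccng1 rose by 1.29 ± 0.11, Cdkn1a by 0.84 ± 0.18 and Dcxr by 0.53 ± 0.13. Mdm2 (0.59 ± 0.19, adjusted p = 0.154) and Phlda3 (0.06 ± 0.08, adjusted p = 0.867) did not pass. Phlda3 signals lay near background in DBA/2J, where changes are compressed. With the erythroid and granulocyte scores as covariates Ccng1 (1.11 ± 0.17, adjusted p = 0.0450) and the p53 list (median 0.086, adjusted p = 0.000807) stayed called, Cdkn1a did not (0.70 ± 0.28, adjusted p = 0.625), and 6 of 12 called lists turned direction, among them DNA replication (0.23). Of 23 interferon-stimulated genes 3 fell (3 adjusted over the list alone), Rsad2 (-2.39 ± 0.36), Isg20 (-1.56 ± 0.27) and Cmpk2 (-1.03 ± 0.19), and the list had an adjusted p = 0.00102, or adjusted p = 0.388 with an estimated correlation. Macrophage and monocyte markers had a median of 0.42 (adjusted p = 8.77e-07, and adjusted p = 0.326 with an estimated correlation), with 0 members called by limma, 6 adjusted over the list alone and 8 higher at an unadjusted p under 0.05. Psmb1 rose by 1.39 ± 0.30, the lysosomal protease Ctsd by 0.98 ± 0.21, Mmp2 by 0.94 ± 0.18 and the endothelial junction gene Cldn5 by 0.88 ± 0.19. Granulocyte markers (median 0.25) had an adjusted p = 0.290, and 0 of 17 passed in limma (0 adjusted over the list alone, 0 at an unadjusted p under 0.05).

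At high dose in DBA/2J 123 features were higher and 84 lower (207, against 2127 at an unadjusted p under 0.05), with 39 and 7 under median scaling. No overlap of the groups was seen for 2162 features (12.6%, 2.86% by chance). Every left-out pool lowered the count, to 14, 87, 48 and 97 without control replicates 1 to 4 and to 49, 15, 87 and 134 without high dose replicates 1 to 4. The calls of Hemgn, Ermap, Cdkn1a, Dcxr and Ctsd were lost in all 8 of these cases (adjusted p up to 0.182), those of Birc5 and Psmb1 in 7 (kept without high dose replicate 3), those of Sptb (kept without high dose replicate 3 or 4) and Cldn5 (kept without control replicate 2 or high dose replicate 4) in 6, and that of Nusap1 without control replicate 1 or high dose replicate 1 or 2, while those of Ccng1, Hbq1b and Rsad2 were lost in none. Isg20 lost its call without control replicate 1 or high dose replicate 2, and so did Mmp2, also without high dose replicate 3, and Cmpk2, also without high dose replicate 1. The erythroid median within the lower and the higher pool numbers was -2.06 and -0.87 and the granulocyte median -0.48 and 0.89, with 0 (1637 at an unadjusted p under 0.05) and 5 features called by limma, and 339 with the pool-number order as a block.

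**Figure D3:**
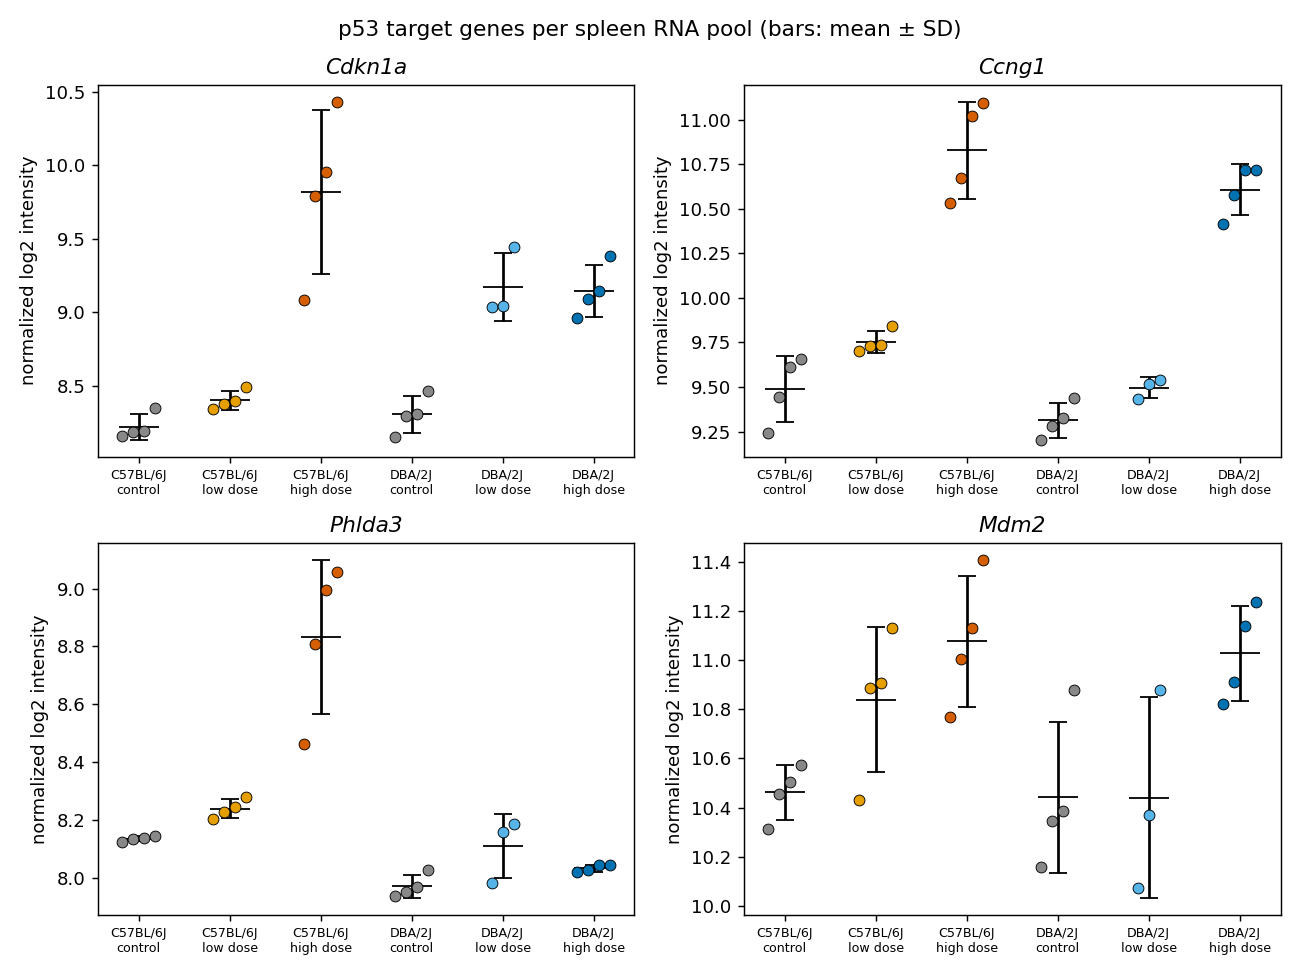
Normalized log2 intensity of Cdkn1a, Ccng1, Phlda3 and Mdm2 in each spleen RNA pool (points), by strain and dose, with horizontal lines for the group mean and bars for ± SD. Ccng1 was higher in the 4 high dose pools of each strain than in every control pool, and Phlda3 changed by 0.70 in C57BL/6J and was measured at 0.06 in DBA/2J, where its signals lay near background.

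The interaction for high dose asked whether the high dose effect differed between strains. Granulocyte transcripts differed most, with Mpo 4.88 ± 0.80 higher in the DBA/2J effect than in the C57BL/6J effect. Of 17 members 5 passed (14 adjusted over the list alone, median 2.52, adjusted p = 5.73e-38, and adjusted p = 0.0107 with an estimated correlation). The granulocyte mean was 11.62 in control and 9.36 in high dose pools of C57BL/6J, and 9.74 and 10.03 in DBA/2J. This difference therefore rests largely on C57BL/6J, where a decrease cannot be told apart from high values in the control pools. Megakaryocyte and platelet markers had 3 of 14 members higher (11 adjusted over the list alone, median 1.01, adjusted p = 1.61e-25, and adjusted p = 0.0203 with an estimated correlation), with Vwf (von Willebrand factor) at 1.97 ± 0.31. Their mean was 9.77 in control, 8.88 in high dose and 8.85 in low dose pools of C57BL/6J, so the same limit holds for this list. Erythroid markers had 4 of 27 members higher (10 adjusted over the list alone, median 1.03), with Car1 (carbonic anhydrase) at 4.30 ± 0.66 and Slc4a1 at 4.08 ± 0.59, an adjusted p = 2.85e-21 and adjusted p = 0.117 with an estimated correlation. Phlda3 was lower in the DBA/2J effect (-0.63 ± 0.12, adjusted p = 0.0298), while Cdkn1a (-0.75 ± 0.26, adjusted p = 0.652), Ccng1 (-0.04 ± 0.16) and Mdm2 (-0.03 ± 0.26) did not pass. In DBA/2J Phlda3 lay between 7.94 and 8.03 in control and 8.02 and 8.04 in high dose pools, near the median of all values (7.88). Changes are compressed there, so a smaller effect in DBA/2J cannot be told apart from a signal near background. C57BL/6J controls were only slightly brighter (8.12 to 8.15), and Phlda3 lay between 8.46 and 9.06 in the high dose pools of that strain. The Phlda3 call was lost in 11 of 16 cases of 1 pool left out and held without C57BL/6J control replicate 3, C57BL/6J high dose replicate 2, 3 or 4 or DBA/2J control replicate 1 (adjusted p up to 0.0831). It was also lost with the covariates (-0.81 ± 0.18, adjusted p = 0.148).

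In this interaction 25 features were higher and 15 lower (40, against 730 at an unadjusted p under 0.05). Median scaling gave 13 and 0, cyclic loess 12 and 3, and normexp with an offset of 50 gave 61 and 3. The count was 23 and 21 without C57BL/6J control replicate 2 or 4, 17, 26 and 25 without C57BL/6J high dose replicate 1, 2 or 4, 14, 14 and 17 without DBA/2J control replicate 2, 3 or 4, and 17, 15 and 14 without DBA/2J high dose replicate 1, 3 or 4. Across genes, which are not independent replicates, the high dose changes of both strains had r = 0.752 and rho = 0.629. Of the called features 65 were higher in both strains (4.60 by chance) and 76 lower in both (2.08 by chance). Within the pool-number parts limma called 0 and 1 features (370 and 1487 at an unadjusted p under 0.05), and 49 with the pool-number order as a block.

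Low dose against control in C57BL/6J again gave lower granulocyte and red cell transcripts. Ltf (-4.18 ± 0.64), Mpo (-4.14 ± 0.57) and Lcn2 (lipocalin, -4.04 ± 0.65) fell most, and of 17 granulocyte markers 11 fell (16 adjusted over the list alone, median -2.31, adjusted p = 2.07e-28, and adjusted p = 0.0401 with an estimated correlation). Of 27 erythroid markers 16 fell (21 adjusted over the list alone, median -1.90), with Klf1 at -3.26 ± 0.52, and the list had an adjusted p = 1.63e-32, or adjusted p = 0.0699 with an estimated correlation. Of 14 megakaryocyte and platelet markers 5 fell (13 adjusted over the list alone, median -0.66, adjusted p = 1.78e-15, and adjusted p = 0.0897 with an estimated correlation), with Gp5 at -1.72 ± 0.31. Mitosis and G2/M genes had 7 of 27 members lower (12 adjusted over the list alone, median -0.85, adjusted p = 1.13e-15, and adjusted p = 0.153 with an estimated correlation). DNA replication had 1 of 29 lower, Rrm1 (12 adjusted over the list alone, median -0.62, adjusted p = 3.51e-16, and adjusted p = 0.170 with an estimated correlation). Rrm1 (-1.50 ± 0.37) kept its call in 1 of 8 cases of 1 pool left out, without control replicate 1 (adjusted p up to 0.162).

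T cell markers rose at low dose in C57BL/6J, 4 of 22 (9 adjusted over the list alone, median 0.34), among them Cd6 (0.99 ± 0.19) and the T cell transcription factor Bcl11b (0.78 ± 0.12). The list had an adjusted p = 1.04e-09, and adjusted p = 0.151 with an estimated correlation. Shifted up as well were B cell (median 0.40, adjusted p = 0.000724), MHC class II (0.36, 0.000724), stromal and endothelial (0.24, 0.0260), germinal centre and plasma cell (0.18, 0.000724), strain-difference (0.14, 0.0349), dendritic cell (0.11, 0.00102) and NK cell (0.05, 0.000724) lists. Pancreas and adipose carry-over (-1.38, 0.00368), NRF2 antioxidant (-0.08, 0.00368), double-strand break repair (-0.07, 0.00368) and oxidative phosphorylation (-0.04, 0.00641) lists were shifted down. With an estimated correlation these 11 lists had adjusted p values between 0.153 and 0.443. With the erythroid and granulocyte scores as covariates 13 of the 17 called lists turned direction, among them T cell (-0.050), B cell (-0.68) and MHC class II (-0.41) markers, and 0 kept call and direction. The pancreas call was lost without control replicate 1 (adjusted p = 0.7996), the stromal call without control replicate 2 or low dose replicate 3 (up to 0.0668) and the strain-difference call without control replicate 2 or 3 or low dose replicate 3 or 4 (up to 0.0957). The p53 list was not called (median 0.03, adjusted p = 0.770), and 1 member, the ribosomal-like gene Rps27l, was lower (-0.40 ± 0.08). Cdkn1a (0.18 ± 0.18), Ccng1 (0.26 ± 0.11), Mdm2 (0.38 ± 0.19) and Phlda3 (0.10 ± 0.08) did not pass, with adjusted p values between 0.273 and 0.706. The Rps27l call was lost without control replicate 2 or 4 or low dose replicate 2 or 4 (adjusted p up to 0.0805). The heat shock gene Hsph1 fell by 1.05 ± 0.21, a call lost without control replicate 2 or low dose replicate 1 (adjusted p up to 0.0558).

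In this comparison 297 features changed, 194 of them lower (against 2530 at an unadjusted p under 0.05). Groups did not overlap for 2083 features (12.1%, 2.86% by chance). Median scaling gave 5 higher and 90 lower, and normexp with an offset of 50 gave 555, of which 454 were lower. The count was 124 and 138 without control replicate 2 or 4, and 133, 139 and 165 without low dose replicate 1, 2 or 4. Lower and higher pool numbers gave a granulocyte median of -2.42 and -2.30 and an erythroid median of -1.95 and -1.77, with 7 and 6 features called, and 456 with the pool-number order as a block.

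High against low dose in C57BL/6J compared the irradiated groups directly, without the control pools. Of 30 p53 targets 4 were higher at high dose (13 adjusted over the list alone, median 0.05, adjusted p = 1.08e-15, and adjusted p = 0.000307 with an estimated correlation), namely Cdkn1a (1.42 ± 0.18), Ccng1 (1.08 ± 0.11), Phlda3 (0.59 ± 0.08) and Rps27l (0.41 ± 0.08). The Rps27l call held only without high dose replicate 3 or 4 (adjusted p up to 0.180 without other pools). With the covariates Cdkn1a (1.35 ± 0.23, adjusted p = 0.0447), Ccng1 (0.96 ± 0.13, adjusted p = 0.00990), Phlda3 (0.61 ± 0.10, adjusted p = 0.0447) and the p53 list (median 0.067, adjusted p = 3.01e-07) stayed called. Of 27 erythroid markers 3 were lower (7 adjusted over the list alone, median -0.79, adjusted p = 1.22e-18, and adjusted p = 0.175 with an estimated correlation), Alas2 (-3.41 ± 0.38), Slc4a1 (-3.33 ± 0.42) and the globin gene Hbb-b2 (-1.85 ± 0.27). Psmb1 was 1.89 ± 0.30 higher. Granulocyte markers had a median of -0.01, a mean of 0.06 and an adjusted p = 0.837, with 0 of 17 passing in limma (0 adjusted over the list alone, 0 at an unadjusted p under 0.05). Immediate-early and heat shock genes (median 0.09, adjusted p = 0.00208, and adjusted p = 0.0335 with an estimated correlation) were shifted up with 0 members called by limma, 1 adjusted over the list alone and 4 higher at an unadjusted p under 0.05.

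High against low dose in C57BL/6J called 22 features higher and 11 lower (33, against 968 at an unadjusted p under 0.05), 7 and 8 under median scaling, and 20 without high dose replicate 1. Fitted on its own 8 arrays, limma called 0 features (1101 at an unadjusted p under 0.05), and the Cdkn1a, Ccng1 and Phlda3 calls were lost there and under median scaling. Groups did not overlap for 750 features (4.37%, 2.86% by chance). Within the pool-number parts limma called 2 and 0 features (574 and 1237 at an unadjusted p under 0.05), and 46 with the pool-number order as a block. The high and low dose changes in C57BL/6J share their controls. Across genes their r was 0.884, which lies inside the range of 95% of 1000 simulations with no effect (-0.216 to 0.897, median 0.542), and 0.708 when the controls were split between both. The covariance was 0.0833 against a simulated 0.00976. Both doses shared 67 higher and 182 lower features, where independent lists would share 3.86 and 4.81 and 100 simulated draws with the shared controls and no effect gave at most 1 and 2. With the controls split in 6 ways, 6 to 17 higher and 11 to 90 lower features were shared.

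Low dose against control in DBA/2J gave granulocyte transcripts higher, not lower. The granule enzyme genes Prtn3 (4.10 ± 0.49), Elane (neutrophil elastase, 4.09 ± 0.56) and Mpo (3.92 ± 0.61) and Lcn2 (3.94 ± 0.71) rose in 3 low dose against 4 control pools. Of 17 granulocyte markers 16 rose (17 adjusted over the list alone, median 3.24, adjusted p = 2.78e-20, and adjusted p = 0.114 with an estimated correlation). Of 14 megakaryocyte and platelet markers 10 rose (14 adjusted over the list alone, median 1.15, adjusted p = 2.33e-11, and adjusted p = 0.114 with an estimated correlation), with Selp (P-selectin) at 1.72 ± 0.34 and Vwf at 1.40 ± 0.24. Of 19 B cell markers 13 fell (16 adjusted over the list alone, median -1.0, adjusted p = 1.36e-11, and adjusted p = 0.114 with an estimated correlation), with Fcer2a, the low affinity IgE receptor, at -1.37 ± 0.26. Of 14 MHC class II genes 8 fell (13 adjusted over the list alone, median -0.82, adjusted p = 8.75e-10, and adjusted p = 0.114 with an estimated correlation), among them the class II transactivator Ciita (-1.35 ± 0.26) and H2-Oa (-1.47 ± 0.29). The calls of Selp, Fcer2a, Ciita and H2-Oa were lost without low dose replicate 1 (adjusted p up to 0.0679).

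Cdkn1a rose by 0.87 ± 0.20 at low dose in DBA/2J, a call lost without control replicate 4 or low dose replicate 1 (adjusted p up to 0.126) and with the erythroid and granulocyte scores as covariates (0.39 ± 0.40, adjusted p = 0.906), while Ccng1 (0.18 ± 0.12), Phlda3 (0.14 ± 0.09) and Mdm2 (-0.00 ± 0.20) did not pass and the p53 list was not called (adjusted p = 0.136). DNA replication had 2 of 29 genes higher (9 adjusted over the list alone, median 0.58, adjusted p = 7.00e-08) and mitosis and G2/M 2 of 27 (10 adjusted over the list alone, median 0.56, adjusted p = 1.47e-06), both with adjusted p = 0.344 with an estimated correlation. Without low dose replicates 1 and 3, which leaves 1 low dose pool, the medians of both turned, to -0.35 and -0.20, the B cell and MHC class II lists lost their calls (-0.13 and -0.024, adjusted p = 0.382 and 0.353), and 4 of the 16 called lists kept call and direction, among them granulocyte (3.10) and megakaryocyte and platelet markers (1.73). The DBA/2J low dose pools were not alike. Across genes, replicates 1 and 3 had r = 0.992 with each other and 0.952 and 0.947 with replicate 2. Leaving out replicates 1 and 3 therefore keeps the pool least like the others of its group. The erythroid list mean was 13.17, 11.60 and 13.31 in replicates 1 to 3, the DNA replication mean 11.02, 9.61 and 11.05, and the B cell mean 9.71, 11.14 and 10.03. The granulocyte mean was 12.91, 12.31 and 12.42, against a control mean of 9.74 ± 0.86 (SD, n = 4).

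At low dose in DBA/2J 728 features were higher and 667 lower (1395, against 4626 at an unadjusted p under 0.05), or 172 and 12 under median scaling. Groups did not overlap for 2153 features (12.5%, 5.71% by chance). The count was 215, 4697 and 487 without low dose replicate 1, 2 or 3 and 2768, 538, 575 and 415 without control replicates 1 to 4. Without low dose replicates 1 and 3 there were 273 higher and 27 lower features, and fitted on its own 7 arrays limma called 0 (2431 at an unadjusted p under 0.05). The higher pool numbers hold 1 low dose pool. In the lower and higher pool numbers the granulocyte median was 2.46 and 3.26 and the erythroid median -0.00 and 1.38, with 2 and 3421 features called, and 2068 with the pool-number order as a block.

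The interaction for low dose compared that effect between strains. All 17 granulocyte markers were higher in the DBA/2J effect (17 adjusted over the list alone, median 6.34, adjusted p = 1.52e-23, and adjusted p = 0.0801 with an estimated correlation), with Mpo at 8.06 ± 0.83 and Lcn2 at 7.98 ± 0.96. The C57BL/6J part of this difference, and of those that follow, cannot be told apart from high or low values in that strain's control pools. All 14 megakaryocyte and platelet markers were higher too (14 adjusted over the list alone, median 2.05, and adjusted p = 0.136 with an estimated correlation), as were 23 of 27 erythroid markers (25 adjusted over the list alone, median 2.32, and adjusted p = 0.143 with an estimated correlation). So were 24 of 29 DNA replication genes (28 adjusted over the list alone, median 1.43, and adjusted p = 0.199 with an estimated correlation) and 20 of 27 mitosis and G2/M genes (23 adjusted over the list alone, median 1.42, and adjusted p = 0.147 with an estimated correlation). Lower in the DBA/2J effect were 15 of 19 B cell markers (17 adjusted over the list alone), 11 of 14 MHC class II genes (13) and 14 of 22 T cell markers (16), each with adjusted p = 0.143 with an estimated correlation. Ccl21a, a chemokine of lymphoid stroma, was at -2.28 ± 0.46 and Fcer2a at -2.23 ± 0.35. Without DBA/2J low dose replicates 1 and 3, which leaves 1 DBA/2J low dose pool, the medians were 5.71 for granulocyte, 1.28 for erythroid, 0.30 for replication, 0.25 for mitosis, -0.59 for B cell, -0.41 for MHC class II and -0.19 for T cell genes.

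This interaction called 1483 features higher and 1554 lower (3037, against 5808 at an unadjusted p under 0.05), 702 and 163 under median scaling. The count was 1119, 5602 and 1464 without DBA/2J low dose replicate 1, 2 or 3, 1981 and 1850 without DBA/2J control replicate 2 or 4, and 351 without low dose replicates 1 and 3. Across genes, the low dose changes of both strains had r = -0.677, with 71 of the features limma called going in opposite directions and 0 in the same, where 4.37 higher and 7.53 lower would be shared by chance. Limma called 0 and 3839 features within the pool-number parts (1773 and 5995 at an unadjusted p under 0.05), and 4022 with the pool-number order as a block.

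High against low dose in DBA/2J gave the largest count of the 9 comparisons. All 29 DNA replication genes (29 adjusted over the list alone, median -1.15), 24 of 27 mitosis and G2/M genes (24, median -1.06), 23 of 27 erythroid markers (25, median -1.82) and 16 of 17 granulocyte markers (16, median -3.01) were lower at high dose. Among them were Rrm2 (-1.95 ± 0.44), Birc5 (-2.46 ± 0.43), Hemgn (-2.79 ± 0.58) and Prtn3 (-4.07 ± 0.49). Higher at high dose were 16 of 19 B cell markers (16 adjusted over the list alone, median 1.18), 12 of 14 MHC class II genes (13, median 0.97) and 14 of 20 macrophage and monocyte markers (14, median 0.92). Without low dose replicates 1 and 3, which leaves 1 low dose pool, the B cell (0.24) and macrophage (0.24) calls were lost. The medians were then -0.15 for replication, -0.21 for mitosis, -0.81 for erythroid and 0.21 for MHC class II genes. With an estimated correlation the replication list had adjusted p = 0.216, and the other 6 lists had adjusted p = 0.203. Ccng1 was higher by 1.11 ± 0.12 and Mdm2 by 0.59 ± 0.20, and Cdkn1a was at -0.03 ± 0.20. The Mdm2 call was lost without high dose replicate 1 or 2 or low dose replicate 1 or 3 (adjusted p up to 0.191). With the covariates Ccng1 (1.00 ± 0.22, adjusted p = 0.530) and Mdm2 (-0.10 ± 0.31) were not called.

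This comparison called 2903 features higher and 2834 lower (5737, against 7516 at an unadjusted p under 0.05), 2237 and 1272 under median scaling. The count was 2973 and 3352 without low dose replicate 1 or 3, and 311 without both (90 higher, 221 lower). Groups did not overlap for 5452 features (31.7%, 5.71% by chance). The pool-number parts gave 131 and 4460 features, and 6578 with the pool-number order as a block. The high and low dose changes in DBA/2J share their controls. Across genes their r was -0.428, against a simulated median of 0.489 with no effect (95% between -0.245 and 0.892), and -0.428 with the controls split, with covariances of -0.0303 and a simulated 0.00941.

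Control mice of both strains were compared to show the strain difference without irradiation. H2-Ea, a class II gene that C57BL/6J mice do not express, was 8.07 ± 0.19 (at least 269-fold) higher in DBA/2J, where all 4 pools detected it. The antitrypsin genes Serpina1b (4.62 ± 0.20) and Serpina1d (4.07 ± 0.19), Hbb-b2 (3.62 ± 0.27) and the guanylate binding gene Gbp2b (3.27 ± 0.16) were also higher. Lower in DBA/2J were the Fc receptor gamma chain Fcer1g (-5.98 ± 0.13, at least 62.1-fold), the protease inhibitor Slpi (-5.72 ± 0.13), Psmb6 (-4.66 ± 0.12), H2-Aa (-4.39 ± 0.26) and the NK receptor Klrd1 (-2.94 ± 0.13, at least 7.63-fold). A sequence variant under a probe can give such values without a change in the transcript.

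Of 17 granulocyte markers 13 were lower in DBA/2J controls (16 adjusted over the list alone, median -2.26, adjusted p = 4.92e-13, and adjusted p = 0.185 with an estimated correlation), such as Prtn3 (-2.62 ± 0.45) and Mpo (-2.57 ± 0.57). The granulocyte mean was 11.62 in C57BL/6J control pools, 9.36 and 9.30 in its high and low dose pools, and 9.74 in DBA/2J controls. A strain difference therefore cannot be told apart from high values in the C57BL/6J control pools. NK cell and cytotoxic markers had 8 of 15 lower and 2 higher (8 and 2 adjusted over the list alone, adjusted p = 0.000125, and adjusted p = 0.185 with an estimated correlation). Immediate-early and heat shock genes were lower (median -0.14, adjusted p = 0.00347, and adjusted p = 0.0505 with an estimated correlation), with Hsph1 at -1.78 ± 0.21. In total 767 features were higher and 951 lower in DBA/2J controls (1718, against 3384 at an unadjusted p under 0.05), or 285 and 988 under median scaling. Groups did not overlap for 2699 features (15.7%, 2.86% by chance). Of 1100 genes with several kept probes, 122 were called by their brightest probe, and 5 were higher and 6 lower by all their probes. Within the pool-number parts 373 and 1082 features were called, and 2035 with the pool-number order as a block.

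An exact permutation test of the list means per pool used no distribution across genes. With 4 pools against 4 the smallest two-sided p is 0.0286, and so it is with 3 against 4. At high dose in C57BL/6J 15 of 23 list means reached exact p = 0.0286 (adjusted 0.0438), among them the erythroid, granulocyte, megakaryocyte, replication, mitosis, p53, NK and T cell lists and also the NRF2 list, which camera did not call. The inflammatory (exact p = 0.371), oxidative phosphorylation (exact p = 0.314) and strain-difference (exact p = 0.0857) means, whose lists camera called, did not reach it. At high dose in DBA/2J 10 means reached exact p = 0.0286 (adjusted 0.0657), among them erythroid, mitosis, replication and p53, and 3 lists called by camera did not. At low dose in C57BL/6J 13 did (adjusted 0.0505), among them erythroid, granulocyte and megakaryocyte, and 4 called by camera did not. At low dose in DBA/2J none of the 16 lists called by camera did, with exact p = 0.0571 (adjusted 0.188) for the granulocyte and megakaryocyte means, and the immediate-early and heat shock mean reached exact p = 0.0286 (adjusted 0.188). The low dose and control pools nevertheless did not overlap in the granulocyte, megakaryocyte, NRF2 and oxidative phosphorylation means. Between the control groups 7 means reached it (adjusted 0.0939), and 3 lists called by camera, the granulocyte list among them, did not. Between the doses 5 means in C57BL/6J (adjusted 0.131) and 16 in DBA/2J (adjusted 0.0411) reached it.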

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

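The counts over other splits of the pools and the test of the strain labels on genes over 2 log2 units apart were fixed before their results were seen, and the other tests were chosen only after.

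Granulocyte markers of the low dose pools lay on opposite sides of their controls in the strains, with a median difference of 6.34 between the DBA/2J and the C57BL/6J effect. Erythroid (2.32), megakaryocyte and platelet (2.05), DNA replication (1.43), mitosis and G2/M (1.42), oxidative phosphorylation (0.26), NRF2 antioxidant (0.23) and double-strand break repair (0.21) genes were also higher in the DBA/2J effect. B cell (-1.53), MHC class II (-1.16), stromal and endothelial (-0.61), macrophage and monocyte (-0.57), strain-difference (-0.54), T cell (-0.48), germinal centre and plasma cell (-0.42), dendritic cell (-0.26) and NK cell (-0.11) genes were lower. Without DBA/2J low dose pools 1 and 3, which leaves 1 such pool, the macrophage and monocyte difference turned (0.068). Stromal (-0.23), strain-difference (-0.16), germinal centre (-0.063), NK cell (-0.044) and double-strand break repair (0.026) differences shrank, while the granulocyte difference was 5.71. At high dose the effects differed in the granulocyte (2.52), erythroid (1.03), megakaryocyte and platelet (1.01), DNA replication (0.17) and mitosis and G2/M (0.0065) lists. The high dose difference was negative for B cell (-0.28), T cell (-0.22), interferon-stimulated (-0.19) and NK cell (-0.081) genes and for the p53 target Phlda3 (-0.63), which lay near background in DBA/2J. With an estimated correlation the granulocyte (adjusted p = 0.0107), megakaryocyte and platelet (0.0203) and NK cell (0.0321) lists kept their call at high dose, and 0 of 17 lists did at low dose, where the lowest adjusted p was 0.0801. The NK cell mean was 8.17 in DBA/2J control and 8.26 in high dose pools, near the median of all values (7.88), against 8.51 and 8.77 in C57BL/6J. A smaller NK cell effect in DBA/2J therefore cannot be told apart from dim signals there. The mitosis call at high dose was lost without C57BL/6J control replicate 2 or DBA/2J control replicate 2 or 4 (adjusted p up to 0.165), and the macrophage call at low dose without DBA/2J low dose replicate 3 (adjusted p = 0.0548). With the erythroid and granulocyte scores as covariates, which take up most of the dose effect by construction, 6 of the 9 lists of the high dose difference turned direction. Among them were DNA replication (-0.44), mitosis and G2/M (-0.46) and B cell (0.63) genes. In all, limma called 3037 features for the low dose difference and 40 for the high dose difference.

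A wrong strain label on a DBA/2J low dose pool was tested first on 85 genes over 2 log2 units apart between the control groups, of which at least a share of 0.753 lay nearer the DBA/2J controls in each pool, a value between the bounds set beforehand that decided nothing. On 14 genes over 4 log2 units apart, a set chosen after that result, the lowest share was 1, with Fcer1g between 7.82 and 7.84 in the 3 pools against 13.82 in C57BL/6J controls, which argues against a wrong strain. A batch that parts each group by its pool numbers is argued against as the whole cause by granulocyte medians of 2.46 and 3.26 within the lower and higher numbers (1 low dose pool in the latter), but 0 low dose or control pools had a number within the range of the other group, so a batch between these groups and the dose cannot be told apart. A share of 0.882 of the granulocyte markers was over 1 log2 unit higher, which restates the pattern and tests nothing. A larger share of granulocyte-lineage cells or their RNA therefore stays open and untested, as do an effect of the low dose and differences between the mice pooled, and so does chance, since 4 of 35 splits of these 7 pools gave as many features as the real 1395, the highest 4648.

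Digestive enzyme transcripts stood out in C57BL/6J control replicate 1 and C57BL/6J high dose replicate 1, whose pancreas list means were 12.78 and 12.98 against 7.88 to 8.16 in the other pools of their groups. A candidate explanation is pancreas tissue taken along with the spleen, which the markers that show the pattern cannot test. All 13 measured acinar genes, a share of 1, were over 2 log2 units above each of the 21 other pools in both, with Cela2a at 15.71 and 15.86 and Ctrb1 at 15.59 and 15.82. A difference of irradiated from control mice is argued against by the 2 groups that these pools belong to. No further biological explanation was tested, and the markers outside the acinar set, Adipoq, Cidec and Ins2, did not stand out.

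Erythroid and granulocyte markers were lower at both doses in C57BL/6J, and both comparisons use the same 4 control pools, whose high values could be the cause. For the erythroid list at high dose this is argued against as the whole cause by the direct difference of high from low dose pools. It was -0.93 in the mean score, with no overlap of the pools. It uses no control pool, so the erythroid decrease at low dose cannot be told apart from high control values. For the granulocyte list the difference between the doses was 0.057, so a decrease after irradiation and high values in these control pools cannot be told apart. The same limit holds for the megakaryocyte and platelet (0.032), DNA replication (-0.16) and mitosis and G2/M (-0.22) lists, whose pools overlapped between the doses. What keeps this open is that no other unirradiated C57BL/6J pools were analysed here. For all these lists a batch between groups stays open because the pool numbers of the groups do not overlap. The strain differences of the effects with this limit use these control pools too, as does the granulocyte difference between the control groups. The same limit holds for them.

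Other splits of the same pools tested chance as the cause of the counts of features. For high dose against control in C57BL/6J 1 of 35 splits, the real one, gave as many as 1069 (the highest other gave 4). The same was seen for high dose against control in DBA/2J (1 of 35, 207 against 17). It was also seen for low dose against control in C57BL/6J (1 of 35, 297 against 6). The same holds for the control groups (1 of 35, 1718 against 34). These real counts lay far above those of all other splits, which argues against chance. It is not excluded, because 35 splits allow no share under 1 of 35 and the shares were not adjusted over the comparisons. For high against low dose in DBA/2J 1 of 35 splits, the real one, gave as many as 5737 (the highest other 2990), but the count was 311 without low dose pools 1 and 3, so it rests on these pools. For high against low dose in C57BL/6J 1 of 35 splits, the real one, gave as many as 33, but the split of the pools by their numbers gave 32, so the count is hardly above that of a possible batch (2 and 0 features by limma within the pool-number parts, 574 and 1237 at an unadjusted p under 0.05, and 46 with the block). For each interaction 100 splits were counted, of which 1 was the real one and the others were random draws. Counting the real one, 3 gave as many as the real 40 (the highest other 267) and 2 as many as the real 3037 (the highest other 3436). Both shares are under 0.05, yet neither real count lies beyond all draws, and the second rests on the low dose pools of DBA/2J, for which chance stays open. The splits in DBA/2J that called 4648, 2990 and 2621 features point to a structure of these pools besides the dose.

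A pool lay far from the 3 others of its group in 13 of 150 tests of 30 measures in 5 groups, where chance gives about 1 in 20. C57BL/6J control replicate 1 also had a macrophage and monocyte mean of 11.02 (others 10.85 to 10.87) and a mean correlation with its group of 0.978 (others 0.983 to 0.984). In C57BL/6J high dose replicate 4 the granulocyte mean was 9.08 (others 9.44 to 9.46). C57BL/6J low dose replicate 2 had a B cell mean of 11.35 (others 11.47 to 11.48), replicate 4 a megakaryocyte and platelet mean of 8.68 (others 8.89 to 8.91), replicate 3 a pancreas mean of 8.06 (others 7.88 to 7.90) and replicate 1 a ribosomal protein mean of 13.60 (others 13.52 to 13.53). DBA/2J control replicate 1 had a double-strand break repair mean of 8.67 (others 8.52 to 8.54) and a strain-difference mean of 10.18 (others 10.30 to 10.31), and DBA/2J control replicate 2 a pancreas mean of 7.99 (others 7.89 to 7.91). The median signal of DBA/2J high dose replicate 1 was 126 (others 116 to 118).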

How the results depend on the processing

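Tests with an offset of 50, with the pool-number order as a block and with covariates were chosen only after the data were seen. So were those without pools with pancreatic transcripts or without DBA/2J low dose pools 1 and 3. Over the alternatives other than the covariates, called lists kept direction and call in 2638 cases, lost the call in 223 and turned in 10, and called genes did so in 9554, 2229 and 17 cases, while named genes not called passed in 15 of 469. The median change of all genes stayed within 0.06 of 0 in each setting. Changes of dim genes are limited by the compression of signals near background. No paired analysis was possible because the replicate numbers were given in accession order and pair no pools across groups. A slide as a block was not run, since no slide is recorded in the sources used here.

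Counts of features moved by over 1.5 times as follows, and the cause was not tested except where fewer arrays or genes entered. Median scaling gave 346 for high dose against control in C57BL/6J and 46 in DBA/2J, 95 and 184 for low dose against control, 13 and 865 for the high and low dose interactions, and 15 and 3509 for high against low dose in C57BL/6J and DBA/2J. Cyclic loess gave 111 and no filter 96 for high dose in DBA/2J, and 15 and 18 for the high dose interaction. With no background correction low dose in C57BL/6J gave 543, and normexp with offset 50 gave 555 there and 64 for the high dose interaction. With only the comparison's groups, which leaves fewer arrays, low dose against control gave 180 in C57BL/6J and 0 in DBA/2J, the low dose interaction 1360, and high against low dose 0 in C57BL/6J and 775 in DBA/2J (both counts of 0 are limma's, against 2431 in DBA/2J and 1101 in C57BL/6J at an unadjusted p under 0.05). Array weights gave 2252 and 903 for high dose, 864 and 5843 for low dose, 185 and 6345 for the interactions, each in the order of the strains or doses above, and 75 for high against low dose in C57BL/6J. The pool-number order as a block gave 339 for high dose in DBA/2J and 456 for low dose in C57BL/6J. In the control groups, 11 genes with several probes passed with all of them in 1 direction.

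With erythroid and granulocyte scores as covariates, limma called 0 features for high dose in C57BL/6J, 2 in DBA/2J, 0 for low dose in C57BL/6J and 0 in DBA/2J, 596 between controls, 3 and 0 for the interactions, and 12 and 1 for high against low dose in C57BL/6J and DBA/2J. At an unadjusted p under 0.05 these 4 counts of 0 were 2284 for high dose in C57BL/6J, 1026 and 1030 for low dose in C57BL/6J and DBA/2J, and 515 for the low dose interaction. The list scores take up most of the dose effect by construction, so single genes were followed only for p53 targets. Of 525 called genes 121 turned sign and 40 stayed called, and of 123 called lists 62 turned and 16 stayed called in the same direction. Lists turned in 13 of 17 cases for high dose and 13 of 17 for low dose in C57BL/6J, 6 of 12 and 3 of 16 in DBA/2J, 4 of 8 between controls, 6 of 9 and 9 of 17 for the interactions, and 6 of 12 and 2 of 15 for high against low dose. Mdm2 for high against low dose in DBA/2J turned to -0.10. Without the pools with pancreatic transcripts high dose in C57BL/6J gave 652 features and high against low dose 21.

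Lists called by camera moved from 17, 12, 17, 16 and 8 to 4, 1, 1, 0 and 0 with the estimated correlation for high dose in C57BL/6J and DBA/2J, low dose in C57BL/6J and DBA/2J and the control groups, from 9 and 17 to 3 and 0 for the interactions, and from 12 and 15 to 2 and 0 for high against low dose. A stricter filter left 3 lists and the pools without pancreatic transcripts 5 between controls. Array weights gave 15 lists for the high dose interaction. The covariates gave 10 and 6 lists for high and low dose in C57BL/6J, 9 for low dose in DBA/2J, 1 between controls, 1 for the low dose interaction and 2 for high against low dose in DBA/2J.

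Without DBA/2J low dose pools 1 and 3, a single low dose pool is left and is assumed to vary like the other groups. That pool, replicate 2, had r = 0.952 and 0.947 with the pools left out, which had r = 0.992 with each other. Low dose then gave 300 features and 10 lists, of which 4 were among the 16 called with all pools and had the same direction, the low dose interaction 351 features and high against low dose 311. For low dose against control in DBA/2J the lists that turned were double-strand break repair (-0.044), DNA replication (-0.35), erythroid (-0.64), germinal centre and plasma cell (0.046), macrophage and monocyte (0.15), mitosis and G2/M (-0.20) and T cell (0.045). The genes were Bard1 (-0.022), Mcm10 (-0.16), Cd72 (0.11), H2-DMb1 (0.036), Ckap2l (-0.11), Ndc80 (-0.0051), Ephx1 (0.22) and Cd2 (0.16). For the low dose interaction the macrophage and monocyte list turned (0.068). For high against low dose in DBA/2J the T cell list (-0.027), Cst3 (-0.0083), Fancd2 (0.0035), Cd72 (-0.060), Zfp36 (-0.066), Bst2 (-0.34), Cd3g (-0.040), Cd3e (-0.037), Ccr7 (-0.15) and Cd2 (-0.21) turned. These directions rest on pools 1 and 3, and the cause of their values was not tested.

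With each pool left out in turn, features ranged from 639 to 966 for high dose in C57BL/6J, 14 to 134 in DBA/2J, 124 to 335 for low dose in C57BL/6J, 215 to 4697 in DBA/2J, 1345 to 1664 between controls, 14 to 56 and 1119 to 5602 for the interactions, and 20 to 37 and 2973 to 7242 for high against low dose. Lists called between controls ranged from 5 to 9. The pancreas list for high against low dose in C57BL/6J, at 1.49, ranged from 0.019 without C57BL/6J high dose replicate 1 to 1.99, and the low value, with the opposite direction of its test, came without the pool that held these transcripts. Leaving out 1 pool ended the call of a called gene in 1131 of 4920 cases.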

Other observations

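The comparisons and left-out pools in this part were fixed beforehand except the setting without DBA/2J low dose pools 1 and 3, the genes were put together only after their values were seen, and no explanation was weighed.

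Stromal and endothelial transcripts differed between the DBA/2J groups without following the dose, with list means of 9.91 in control, 9.52 in low dose and 10.18 in high dose pools. B cell (11.22, 10.29 and 11.35), MHC class II (12.31, 11.47 and 12.50) and macrophage and monocyte means (10.81, 10.46 and 11.22) were lowest in the low dose pools as well, and the granulocyte mean (9.74, 12.54 and 10.03) was highest there. The low dose pools differed, and the highest macrophage and monocyte mean among them (11.02) lay above every control pool (up to 10.95). At high dose 1 of 18 markers rose against control (2 adjusted over the list alone, median 0.26, adjusted p = 0.000368, and adjusted p = 0.354 with an estimated correlation). Of the 18 markers 4 fell at low dose (6 adjusted over the list alone, median -0.38, adjusted p = 0.00137, and adjusted p = 0.313 with an estimated correlation), among them the B cell chemokine Cxcl13 (-1.10 ± 0.21), and 11 were higher at high than at low dose (11 adjusted over the list alone, median 0.67, adjusted p = 9.08e-05, and adjusted p = 0.203 with an estimated correlation), with Ccl21a at 1.72 ± 0.34, Cxcl13 at 1.40 ± 0.21 and Stab2, a scavenger receptor of sinus endothelium, at 1.37 ± 0.24. The Cxcl13 call at low dose was lost without low dose replicate 1 (adjusted p up to 0.0547), and those of these 3 genes between the doses in none of the 7 cases of 1 pool left out. Without DBA/2J low dose pools 1 and 3, which leaves 1 low dose pool, the stromal list median was 0.0048 at low dose and 0.19 between the doses. The stromal decrease at low dose therefore rests on those pools. At low dose the B cell (-0.13) and MHC class II (-0.024) medians also came near 0 and the macrophage and monocyte median turned (0.15). The granulocyte median stayed high (3.10). Genes of oxidative phosphorylation went the other way in DBA/2J, with 3 of 23 higher at low dose (4 adjusted over the list alone, median 0.19, adjusted p = 0.00022, and adjusted p = 0.114 with an estimated correlation) and 9 lower at high than at low dose (9 adjusted over the list alone, median -0.22, adjusted p = 0.000113, and adjusted p = 0.203 with an estimated correlation). Without the same pools, which leaves 1 low dose pool, these list medians were 0.19 and -0.20.

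The heat shock gene Hsph1 was lower in DBA/2J than in C57BL/6J controls (-1.78 ± 0.21). At low dose it fell in C57BL/6J (-1.05 ± 0.21) and rose in DBA/2J (1.14 ± 0.22), a difference of 2.20 ± 0.30 with limma's adjusted p = 0.000458. The C57BL/6J call was lost without control replicate 2 or low dose replicate 1 (adjusted p up to 0.0558), and the DBA/2J call without DBA/2J low dose pools 1 and 3 (1.10, adjusted p = 0.146). Hspd1 of the same list, the immediate-early and heat shock genes, had a low dose difference of 1.27 ± 0.25. That list was not called for the low dose difference. The strain difference and the low dose changes share the control pools, so they cannot be told apart from high or low values in those pools.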
